A study of Homo sapiens with 96 samples.

How the data were processed

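RNA was sequenced from primary orbital fibroblasts of 8 donors with thyroid eye disease, named A to H here. Per the labels, cells were held in low serum and received 1 of 6 treatments: vehicle; IL-11 at 10 ng/mL; IL-11 with LASN01 at 1 µg/mL; IL-11 with IGF-1 at 100 ng/mL; that pair with LASN01; or that pair with teprotumumab at 10 µg/mL. The antibodies were added 1 h before the ligands. RNA was taken at 6 h and at 48 h, which gives 12 groups of 8 libraries and 96 libraries in all. Each donor has 1 library per group. Library numbers 1 to 48 belong to donors A to D and 49 to 96 to donors E to H; the labels do not call this a batch. Titles of 2 libraries of a single donor at 6 h shorten the antibody code and were read as the LASN01 arms.

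Per the labels, libraries were made from poly-A RNA without strand information and read as pairs on an Illumina instrument, base calls came from CASAVA and reads were aligned to hg38 with HISAT2, with no versions stated. The authors deposited a matrix of FPKM (fragments per kilobase of gene and per library size) for 58735 genes with a length per gene. FPKM multiplied by length was a whole multiple of 1 step size in every library (100% of values within 0.001 of a whole number), which gave back whole fragments per gene. No deposited counts were used and no model for counts was fitted to them other than limma-voom as an alternative. Library size behind the FPKM was 0.827 to 1.13 times the summed fragments, and FPKM as deposited already had equal median ratios between libraries.

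Depth was 14.1 to 34.5 M fragments per library, median 17.4 M, with 15977 to 22753 genes above 0 (median 20913.5). Genes of chromosome Y, XIST and TSIX (520) were removed before any fit. Genes with FPKM of at least 1 in at least 8 of 96 libraries were tested: 12713, of which 11013 code for protein. Symbols are those of the deposited values (CTGF is CCN2, CYR61 is CCN1, NOV is CCN3, WISP2 is CCN5), and 175 symbols occur more than once, so genes were matched by Ensembl ID. As a pairing check, each library was compared with all others after removal of group means; 0 libraries had their best match in another donor.

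Log2(FPKM + 0.5) was fitted gene by gene with limma 3.58.1 in R 4.3.3 (data.table package version 1.17.8), with the 48 libraries of a time in 1 fit, arm as the factor and donor as a block, followed by empirical Bayes moderation with trend and robust options. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over the tested genes of a comparison, two-sided). Differences between times used all 96 libraries, with 12 groups and 16 donor-by-time blocks; vehicle at 48 h against vehicle at 6 h used the donor as the block. Standard errors are those of the fit. The IL-11 response score of a donor is the mean log2 value of the genes that rose minus that of the genes that fell in IL-11 versus vehicle, called in the other 7 donors only; the IGF-1 response score uses IL-11 + IGF-1 versus IL-11 in the same way. Score differences were tested with an exact two-sided sign-flip test over 8 donors (256 sign patterns, smallest p 0.00781).

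Before the data were examined, 26 gene lists were fixed from textbook knowledge: JAK-STAT3 targets, acute phase and complement, IL-6 family, IGF axis, extracellular matrix, myofibroblast contractile genes, hyaluronan and proteoglycans, adipogenesis, cytokines and chemokines, matrix proteases, orbital fibroblast genes, cell cycle, sterol and fatty acid synthesis, FOXO targets, ATF4 and amino acid genes, glycolysis and hypoxia, immediate early genes, interferon-stimulated genes, heat shock, mitochondrially encoded mRNAs, and markers of endothelium, leukocytes, skeletal muscle, pericytes, epithelium and Schwann cells. Each was tested with camera of limma at a preset correlation of 0.01 and with the correlation estimated, adjusted over the lists of a comparison. Estimated correlations reached 0.429 for sterol genes at 48 h and 0.978 for mitochondrially encoded mRNAs at 6 h. The p values at the preset correlation can therefore overstate the evidence. The leukocyte list had 0 measured members, so 25 lists were tested. TSHR was not among the tested genes.

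The rule for genes named in the text was also set before the data were examined. In each of the 6 main comparisons per time, up to 8 risen and 8 fallen protein-coding genes with the largest change were taken. They had to pass the test, reach a mean FPKM of 2 in an arm and move the same way in at least 7 of 8 donors. Up to 4 passing members of each list with the smallest p followed, and IL11, IL11RA, IL6ST, IGF1R, SOCS3, IL6, HAS2, COL1A1 and ACTA2 were taken in any case. Other comparisons took up to 4 and 4, or the 3 genes with the smallest p where fewer than 3 passed. The text gives part of these, and some single genes are not reported here.

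Other settings fixed before the data were examined were: no donor block, pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, only the 2 arms compared in the fit, plain empirical Bayes, limma-voom on the recovered fragments, each donor left out, each run of library numbers alone, and scores from the top 50 genes. Chosen after seeing the data were: leaving out the IL-11 6 h library of donor F, leaving out that library with the teprotumumab libraries of donors E and F at 6 h, scaling to summed fragments, the comparison of IL-11 + IGF-1 + LASN01 with IL-11 + LASN01, and the overlaps between comparisons that share no library. Limma-voom took the summed fragments as library size with no further normalization, so it shares its scaling with the setting scaled to summed fragments. For the test against chance, the labels of both arms were swapped within donors in 40 ways, the real one included.

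The steps were tested on simulated data with the design of the 48 libraries at 6 h and 200 genes changed in the tested arm. Most real comparisons called more genes, which loosens the threshold on p, so the rates below can understate what was called there. Of tested genes given a 1.1-fold change, 4 of 47 were called; at 1.25-fold 36 of 48, at 1.5-fold 45 of 47 and at 2-fold 45 of 46. Of 12506 unchanged genes, 7 were called, and a score with 25% left by construction came back as 24.3 ± 1.69% (n = 8). Variants, allele-specific expression and splicing were not analysed here, and neither were reads.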

Results

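Orbital fibroblasts of 8 donors with thyroid eye disease were profiled by RNA-seq after 6 h and 48 h in 6 arms, 96 libraries with 14.1 to 34.5 M fragments each (median 17.4 M). The comparisons asked what IL-11 changes in these cells, what IGF-1 adds to it, and how much of each response is left with LASN01, an antibody to the IL-11 receptor, or teprotumumab, an antibody to the IGF-1 receptor. The antibody doses differed, 1 µg/mL for LASN01 and 10 µg/mL for teprotumumab. In each comparison 12713 genes were tested with donor as a block. Changes are log2 fold changes with the standard error of the fit, levels are mean ± SD of FPKM over 8 donors, and p values are two-sided. Adjusted p values of genes come from limma, and those of gene lists from camera.

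The time in culture and the donor set most of the variation. The 1st principal component held 38.9% of the variance, 97.7% of it between 6 h and 48 h, and the 2nd held 8.03%, 69% of it between donors and 60.1% between the runs of library numbers 1 to 48 and 49 to 96. Deviations from the group mean correlated between libraries of a donor at the same time with a median r of 0.64, against -0.1 between donors. Fibroblast transcripts were abundant: COL1A1 stood at 3460 ± 554 FPKM and FN1 at 1890 ± 448 FPKM in vehicle at 6 h. None of the 13 leukocyte markers reached the level for testing. KRT14, a keratin of basal epithelium, reached 138 ± 97.5 FPKM in vehicle at 6 h, with a wide spread between donors. Among libraries that stood apart, IL-11 at 6 h of donor F had 15977 genes above 0, 0.0919% mitochondrial fragments and 28.6% of its fragments in 10 genes. Most counts of genes called at 6 h are therefore also given without it, while overlaps between comparisons are not. That library also enters the error of 6 h comparisons without its arm, since 1 fit held all 48 libraries of a time. Counts at 6 h and at 48 h therefore do not compare the size of effects. A further setting also left out the teprotumumab libraries of donors E and F.

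After 6 h with IL-11, genes of the JAK-STAT3 pathway, which IL-11 and related cytokines use, rose together with interferon-stimulated genes. SOCS3, the feedback inhibitor of this pathway (ENSG00000184557, chr17:78356778-78360077, hg38), rose from 6.97 ± 2.18 to 28.2 ± 5.19 FPKM (1.97 ± 0.08, adjusted p = 5.88e-22). NNMT, an enzyme of nicotinamide metabolism, rose by 1.54 ± 0.07, the transcription factor CEBPD by 1.52 ± 0.07 and JUNB by 1.39 ± 0.07. Of 21 measured JAK-STAT3 genes 16 rose and 0 fell; adjusted over the list alone, 17 rose and 1 fell (camera adjusted p = 3.13e-29). The oncostatin M receptor OSMR rose by 0.88 ± 0.08 and IL6 by 0.75 ± 0.14, while IL11 itself fell by 0.32 ± 0.08 (adjusted p = 0.00659). IL6 was low, at 0.472 ± 0.261 FPKM in vehicle and 1.19 ± 0.659 with IL-11, where the 0.5 added before the log shrinks the change. IL11RA (-0.06 ± 0.09, adjusted p = 0.716) and IL6ST (0.07 ± 0.09, adjusted p = 0.644) did not pass.

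Of 22 interferon-stimulated genes 14 rose at 6 h (18 adjusted over the list alone, camera adjusted p = 4.64e-21), among them the GTPases GBP2 (1.2 ± 0.08) and GBP1 (1.13 ± 0.08), and IFIT3 (0.82 ± 0.05). The lipid scramblase PLSCR1 (1.48 ± 0.08) and the apolipoprotein L gene APOL2 (1.28 ± 0.06) were among the largest changes. Of 12 cytokine and chemokine genes 5 rose and 1 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.00065): the monocyte chemoattractant CCL2 rose from 1.8 ± 0.409 to 5.11 ± 2.11 FPKM and the alarmin IL33 from 1.62 ± 0.688 to 3.17 ± 1.76. Acute phase genes included the pentraxin PTX3 (0.68 ± 0.12), with 5 of 10 risen (6 adjusted over the list alone, camera adjusted p = 1.8e-05).

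Genes of the myofibroblast contractile list moved the other way. That list also holds ITGA11, CDH2, TGFB1 and TGFB2, which do not encode contractile proteins. Of 15 myofibroblast contractile genes 7 fell and 0 rose at 6 h (8 adjusted over the list alone, camera adjusted p = 1.8e-05): the actin-binding LMOD1 (-0.53 ± 0.07), the collagen-binding integrin ITGA11 (-0.26 ± 0.04) and TGFB1 (-0.22 ± 0.06). Smooth muscle actin, ACTA2, stood at -0.15 ± 0.06 (adjusted p = 0.12). Of 26 cell cycle genes 10 fell (15 adjusted over the list alone, camera adjusted p = 7.59e-07, but adjusted p = 0.13 with an estimated correlation), among them MCM4 (-0.35 ± 0.04). Of 13 orbital fibroblast genes 2 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.161), PDGFRB (-0.36 ± 0.05) and CD34 (-0.35 ± 0.06). FAM180A stood at -0.99 ± 0.24. Without the donor F library it was -0.59. Of 4 epithelial markers 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.00845, adjusted p = 0.142 with an estimated correlation), KRT18 by 0.48 ± 0.06. HAS2, which makes hyaluronan, did not pass (-0.08 ± 0.07, adjusted p = 0.487). Of 19 hyaluronan and proteoglycan genes 4 rose (5 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.356), and their median (-0.02) and mean (0.05) differed in sign.

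In all, 708 genes rose and 656 fell at 6 h, 768 of them the same way in all 8 donors, 24 and 2 by at least 2-fold. Without the donor F library 808 rose and 730 fell; without the donor block 121 and 12; limma-voom called 534 and 752; library numbers 1 to 48 alone gave 1324 genes and 49 to 96 gave 169. The 13 mitochondrially encoded mRNAs had a median of -0.62 with 0 called (camera adjusted p = 0.00745, adjusted p = 0.612 with an estimated correlation), beside the low mitochondrial share of the donor F library.

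At 48 h complement genes were among those raised most by IL-11. C3, the central complement component (ENSG00000125730, chr19:6677704-6730562), rose from 6.35 ± 2.06 to 59.9 ± 19.5 FPKM (3.13 ± 0.09, adjusted p = 2.18e-26). PLA2G2A, a secreted phospholipase, rose by 4.06 ± 0.25 to 44.2 ± 76.4 FPKM, the chitinase-like CHI3L1 by 2.66 ± 0.14 and the transcription factor NFE2 by 2.94 ± 0.14. Of 10 acute phase and complement genes 9 rose and 1 fell (also 9 and 1 adjusted over the list alone, camera adjusted p = 3.73e-14). C1R stood at 1.27 ± 0.05, C1S at 1.16 ± 0.06 and the C1 inhibitor SERPING1 at 0.89 ± 0.05. Of 21 JAK-STAT3 genes 18 rose and 1 fell at 48 h, over all genes and adjusted over the list alone (camera adjusted p = 3.83e-28), with SOCS3 at 2.11 ± 0.06.

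Hyaluronan and matrix genes moved at 48 h. HAS2 (ENSG00000170961, chr8:121612116-121641390) rose from 2.22 ± 0.832 to 5.14 ± 3.35 FPKM (0.95 ± 0.13, adjusted p = 1.37e-07), and the hyaluronan receptor CD44 and the proteoglycan VCAN each by 0.37 ± 0.04. In that list 8 of 19 genes rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.02). Matrix genes split: of 25, 6 rose and 11 fell (7 and 13 adjusted over the list alone, camera adjusted p = 0.0734), with SPARC (-0.41 ± 0.03) and COL3A1 (-0.26 ± 0.03) fallen and THBS2 (0.48 ± 0.06) risen. COL1A1 did not pass (-0.11 ± 0.04, adjusted p = 0.0614). Of 15 matrix proteases and inhibitors 6 rose and 5 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.0519), with ADAMTS1 at 1.04 ± 0.05 and the urokinase PLAU at 0.91 ± 0.06.

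Contractile genes were lower at 48 h: 10 of 15 fell and 0 rose (12 adjusted over the list alone, camera adjusted p = 1.09e-07, adjusted p = 0.0422 with an estimated correlation). ITGA11 stood at -0.49 ± 0.03, TPM1 at -0.51 ± 0.06 and ACTA2 at -0.33 ± 0.11 (adjusted p = 0.0235). Beside them 3 of 6 measured pericyte markers rose (camera adjusted p = 0.02, adjusted p = 0.0524 with an estimated correlation), ABCC9 by 0.87 ± 0.07, and so did 3 of 3 Schwann cell markers (camera adjusted p = 0.00374). Of 3 measured skeletal muscle markers 2 fell (camera adjusted p = 0.026, adjusted p = 0.0524 with an estimated correlation). Of 13 orbital fibroblast genes 8 rose and 5 fell, with THY1 at 0.53 ± 0.06 and CD34 at -0.71 ± 0.08 (camera adjusted p = 0.441); the counts adjusted over the list alone were the same. Of 12 cytokine genes 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.91e-05). The chemokine CXCL12 rose by 0.58 ± 0.06. Of 22 interferon-stimulated genes 13 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 6.61e-10, adjusted p = 0.0292 with an estimated correlation), with IFITM1 at 1.44 ± 0.09. In all, 1390 genes rose and 1344 fell, 1760 the same way in all 8 donors; without the donor block 248 and 56 were called, and library numbers 1 to 48 and 49 to 96 alone gave 1733 and 1323 genes.

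**Figure D1:**
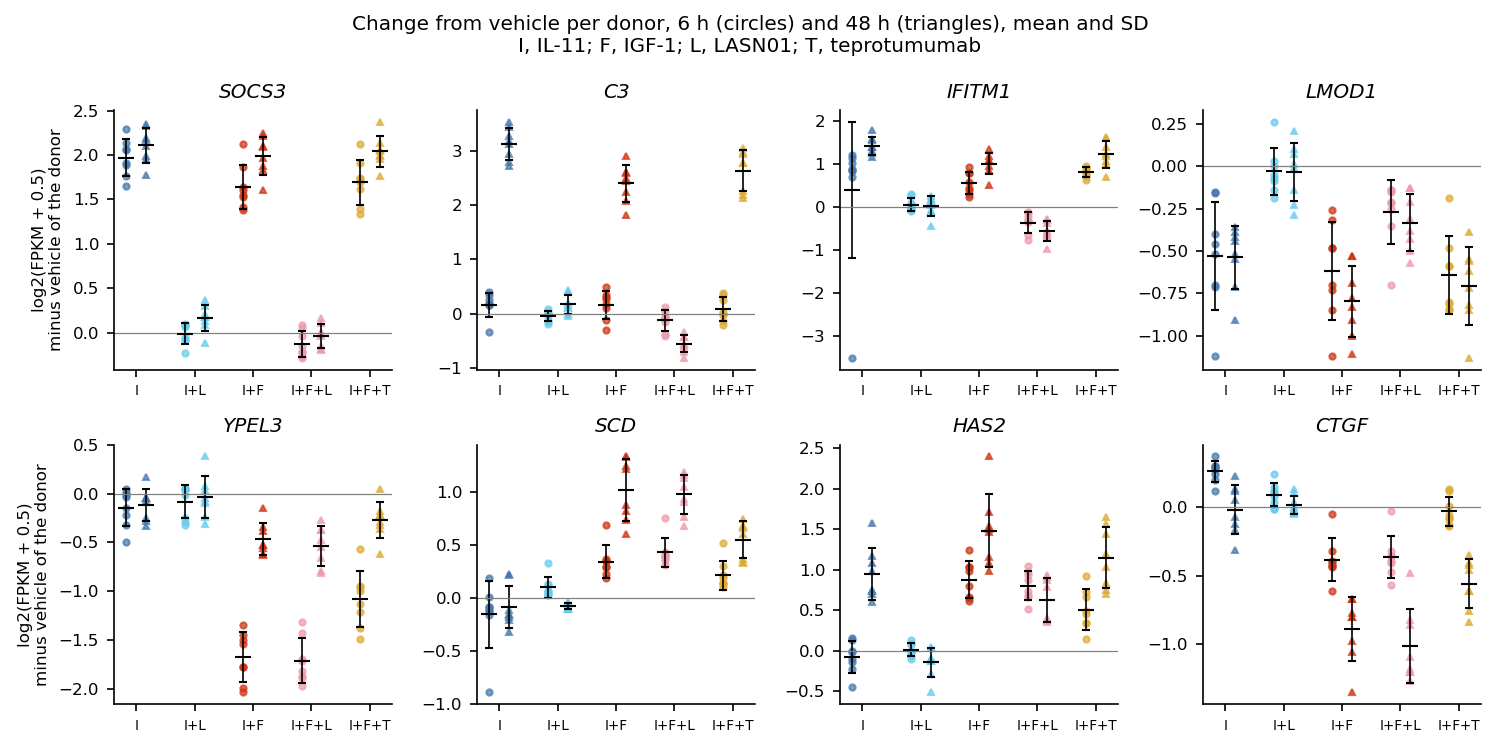
Change from vehicle in log2(FPKM + 0.5) for 8 genes, 1 point per donor with mean and SD (n = 8), for the 5 treated arms at 6 h (circles) and 48 h (triangles). SOCS3 lies near 0 in both arms with LASN01, and YPEL3 and SCD in the teprotumumab arm lie between the IL-11 arm and the IL-11 + IGF-1 arm.

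LASN01 moved the genes of the IL-11 response back at both times, though few cell cycle genes were called at 6 h. At 6 h SOCS3 stood at 6.94 ± 2.42 FPKM with the antibody against 28.2 ± 5.19 without (-1.98 ± 0.08, adjusted p = 4.85e-22), and NNMT (-1.51 ± 0.07), JUNB (-1.33 ± 0.07) and GBP2 (-1.18 ± 0.08) were lower. Of 21 JAK-STAT3 genes 17 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.32e-32), and of 22 interferon-stimulated genes 15 fell (17 adjusted over the list alone, camera adjusted p = 7.62e-27). IL6 fell by 0.75 ± 0.14, to a low 0.467 ± 0.238 FPKM, and CCL2 by 0.95 ± 0.13. In the cytokine list 5 of 12 genes fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000163). Of 15 contractile genes 5 rose (8 adjusted over the list alone, camera adjusted p = 1.73e-05), with LMOD1 at 0.5 ± 0.07 and TGFB2, a growth factor, at 0.61 ± 0.13. The Wnt inhibitor DKK1 rose by 0.49 ± 0.05. Of 26 cell cycle genes 2 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0999). With IL-11 and LASN01 against vehicle their median was still -0.11, against -0.18 with IL-11 alone. In that comparison 0 were called (camera adjusted p = 5.73e-12, adjusted p = 0.128 with an estimated correlation).

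At 48 h C3 was at 7.31 ± 2.95 FPKM with LASN01 against 59.9 ± 19.5 without (-2.96 ± 0.09), and PLA2G2A (-3.8 ± 0.25), CHI3L1 (-2.61 ± 0.14) and SOCS3 (-1.94 ± 0.06) fell. HAS2 fell by 1.09 ± 0.13 to 1.97 ± 0.726 FPKM (adjusted p = 7.05e-09), CD44 by 0.39 ± 0.04 and VCAN by 0.42 ± 0.04. Of 19 hyaluronan genes 9 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0117). Of 10 acute phase genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 9.96e-15). Contractile genes rose, 12 of 15 (13 adjusted over the list alone, camera adjusted p = 3.84e-09), with TPM1 at 0.52 ± 0.06 and ACTA2 at 0.35 ± 0.11 (adjusted p = 0.0165). SPARC (0.46 ± 0.03), COL3A1 (0.28 ± 0.03) and COL1A1 (0.19 ± 0.04, adjusted p = 0.000727) rose, with 13 of 25 matrix genes risen and 7 fallen (15 and 7 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.159 with an estimated correlation). Of 26 cell cycle genes 18 rose (22 adjusted over the list alone, camera adjusted p = 2.75e-08, adjusted p = 0.12 with an estimated correlation), CDC20 by 0.56 ± 0.09. The pericyte markers ABCC9 (-0.85 ± 0.07) and KCNJ8 (-0.5 ± 0.09) fell, and IL11RA rose by 0.23 ± 0.07 (adjusted p = 0.0181).

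LASN01 changed 430 genes upward and 552 downward at 6 h, and 1293 and 1358 at 48 h. Without the donor F library 439 rose and 614 fell at 6 h; without the donor block 4 and 113 were called at 6 h and 62 and 215 at 48 h. The runs of library numbers alone gave 830 and 135 genes at 6 h and 1635 and 1339 at 48 h. Against vehicle, cells with IL-11 and LASN01 had 0 genes called at 6 h (504 at an unadjusted p under 0.05 in limma, 0 by limma-voom) and 0 at 48 h (573 at an unadjusted p under 0.05, 2 by limma-voom, and 1 without donor A). The 504 and 573 are below the share of 0.05 that chance gives on average among 12713 tested genes. Among the smallest p were at 6 h those of ZNF502 (0.24 ± 0.06, adjusted p = 0.857) and REXO5 (-0.31 ± 0.08, adjusted p = 0.975), and at 48 h to TRIM45 (0.34 ± 0.07, adjusted p = 0.0863), DDIT3 (-0.24 ± 0.05, adjusted p = 0.0972) and AP001330.5 (-0.73 ± 0.16, adjusted p = 0.2). Camera called 3 lists at 6 h and 5 at 48 h in this comparison, 0 of them with an estimated correlation. A count of 0 does not show that the arms are equal.

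Adding IGF-1 to IL-11 lowered targets of FOXO transcription factors, which insulin and IGF-1 signals keep out of the nucleus, and raised genes of lipid synthesis. At 6 h the FOXO targets KLHL24 (-1.41 ± 0.08), CCNG2 (-1.08 ± 0.09) and the PI3K inhibitor PIK3IP1 (-1.04 ± 0.09) fell. Outside that list, YPEL3, a growth-arrest gene (ENSG00000090238), fell from 6 ± 0.803 to 1.77 ± 0.448 FPKM (-1.53 ± 0.07, adjusted p = 9.14e-19), and HBP1 fell by 1.16 ± 0.06. Of 20 FOXO targets 16 fell and 0 rose, the same number adjusted over the list alone (camera adjusted p = 1.26e-15). The receptor genes IGF1R (-0.68 ± 0.04, adjusted p = 1.05e-15) and INSR (-0.54 ± 0.05) and the adaptor IRS2 (-0.67 ± 0.07) fell, with 7 of 15 genes of the IGF axis fallen and 2 risen (10 and 2 adjusted over the list alone, camera adjusted p = 0.000286). HAS2 rose from 13.3 ± 4.27 to 26.3 ± 7.77 FPKM (0.96 ± 0.07, adjusted p = 1.95e-13). The EGF family ligand EPGN rose by 0.89 ± 0.13.

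Of 26 sterol and fatty acid genes 18 rose at 6 h and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 5.69e-10). Among them were ACACA (0.33 ± 0.04), SCD (0.5 ± 0.07) and SREBF1 (0.38 ± 0.06). Matrix genes fell: 10 of 25, with 1 risen (13 and 1 adjusted over the list alone, camera adjusted p = 0.000243), the connective tissue growth factor CTGF from 1010 ± 210 to 653 ± 146 FPKM (-0.64 ± 0.05). Interferon-stimulated genes fell in part, 9 of 22 with 1 risen, over all genes and adjusted over the list alone (camera adjusted p = 0.00196), IFIT2 by -0.71 ± 0.06. SOCS3 (-0.33 ± 0.08, adjusted p = 0.000982) and CEBPD (-0.7 ± 0.07) were lower than with IL-11 alone. Heat shock genes rose in part, 4 of 12 with 1 fallen (5 and 1 adjusted over the list alone, camera adjusted p = 0.00936), HSPA8 by 0.59 ± 0.06. Of 3 Schwann cell markers 2 fell (3 adjusted over the list alone, camera adjusted p = 0.0463, adjusted p = 0.0916 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 0 were called, over all genes and adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.0463, adjusted p = 0.639 with an estimated correlation) and -0.07 without the donor F library.

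By 48 h nearly the whole lipid synthesis list had risen. SCD, the stearoyl-CoA desaturase (ENSG00000099194, chr10:100347124-100364834), rose from 96.7 ± 35.9 to 205 ± 66 FPKM (1.11 ± 0.07, adjusted p = 4.24e-16). In all 25 of 26 genes of the list rose, over all genes and adjusted over the list alone (camera adjusted p = 1e-29, adjusted p = 0.0069 with an estimated correlation). Among them were FADS2 (0.69 ± 0.06), HMGCS1 (0.57 ± 0.05) and FDPS (0.52 ± 0.05). Of 20 ATF4 and amino acid genes 12 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 6.94e-07), TRIB3 by 0.55 ± 0.07 and SESN2 by 0.43 ± 0.05. Matrix genes now rose, 12 of 25 with 5 fallen (13 and 5 adjusted over the list alone, camera adjusted p = 0.000172, adjusted p = 0.0707 with an estimated correlation): COL6A3 by 0.6 ± 0.05, SPARC by 0.41 ± 0.03, COL3A1 by 0.37 ± 0.03 and COL1A1 by 0.22 ± 0.04 (adjusted p = 9.01e-05), while CTGF fell (-0.87 ± 0.07). HAS2 (0.53 ± 0.13, adjusted p = 0.00134) and TNFAIP6, a hyaluronan-binding protein (0.99 ± 0.15), rose.

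Complement genes were lower with IGF-1 than with IL-11 alone at 48 h: 6 of 10 acute phase genes fell, over all genes and adjusted over the list alone (camera adjusted p = 6.94e-07), C3 by -0.73 ± 0.09 and SERPING1 by -0.7 ± 0.05. FOXO targets fell in 8 of 20, with 2 risen (11 and 2 adjusted over the list alone, camera adjusted p = 0.00901). Of 20 immediate early genes 10 fell (12 adjusted over the list alone, camera adjusted p = 0.000149, adjusted p = 0.0526 with an estimated correlation), DUSP1 by -0.47 ± 0.06, and 10 of 13 mitochondrially encoded mRNAs fell (11 adjusted over the list alone, camera adjusted p = 6.11e-05, adjusted p = 0.237 with an estimated correlation). SOCS3 did not pass (-0.12 ± 0.06, adjusted p = 0.148). Skeletal muscle markers fell, 3 of 3 over all genes and adjusted over the list alone (camera adjusted p = 0.0108), TNNT3 by -0.64 ± 0.07.

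IGF-1 raised 1531 genes and lowered 1644 at 6 h, and 1472 and 1677 at 48 h. At 6 h the values were 1770 and 1876 without the donor F library and 388 and 346 without the donor block. Scaling to summed fragments gave 2675 and 867, and limma-voom, which uses the same scaling, 2775 and 917. At 48 h 88 rose and 92 fell without the donor block. Numbers 1 to 48 and 49 to 96 alone gave 2919 and 674 genes at 6 h and 2118 and 1133 at 48 h.

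Against vehicle, IL-11 with IGF-1 joined both responses. At 6 h SOCS3 rose by 1.64 ± 0.08 and the interleukin-1 receptor IL1R1 by 1.35 ± 0.07, while YPEL3 fell by 1.67 ± 0.07 and the muscle ubiquitin ligase FBXO32 by 1.3 ± 0.06. Of the lists, 15 of 21 JAK-STAT3 genes rose (15 risen and 1 fallen adjusted over the list alone, camera adjusted p = 7.14e-13) and 15 of 20 FOXO targets fell, with 1 risen (16 and 1 adjusted over the list alone, camera adjusted p = 4.61e-11). At 48 h C3 rose by 2.4 ± 0.09, HAS2 by 1.48 ± 0.13 to 7.61 ± 4.09 FPKM, TNFAIP6 by 1.56 ± 0.15, the chloride channel regulator CLCA2 by 2.41 ± 0.12 and COL6A3 by 0.85 ± 0.05. CTGF (-0.89 ± 0.07), ZNF488 (-1.44 ± 0.07) and the bone proteoglycan OMD (-1.43 ± 0.13) fell. Of 22 glycolysis and hypoxia genes 13 rose and 4 fell at 48 h, over all genes and adjusted over the list alone (camera adjusted p = 0.000866, adjusted p = 0.0853 with an estimated correlation), PKM by 0.56 ± 0.04. Counts were 1873 risen and 1980 fallen at 6 h and 2470 and 2610 at 48 h. At 6 h 2421 and 2805 were called without the donor F library, 665 and 440 without the donor block, and 2416 and 1281 with scaling to summed fragments (2476 and 1325 by limma-voom); at 48 h 631 and 548 without the donor block. Library numbers 1 to 48 and 49 to 96 alone gave 4364 and 850 genes at 6 h and 3933 and 2805 at 48 h.

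**Figure D2:**
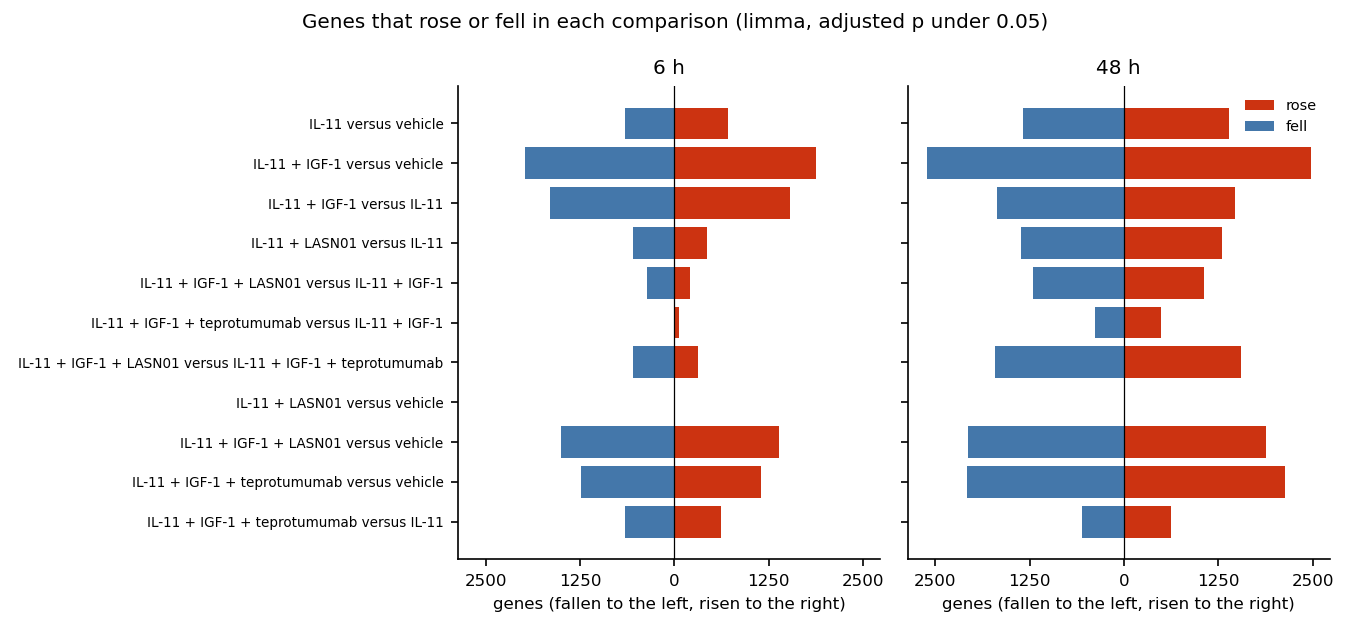
Number of genes called at an adjusted p under 0.05 in each comparison at 6 h and 48 h (8 donors per arm), genes that fell to the left of 0 and genes that rose to the right. Teprotumumab against IL-11 + IGF-1 gave 75 genes at 6 h and 873 at 48 h, LASN01 against the same arm 568 and 2267, and IL-11 + LASN01 against vehicle 0 at both times.

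In the presence of IGF-1, LASN01 lowered genes of the IL-11 response, while FOXO targets and sterol genes were mostly not called. At 6 h SOCS3 fell from 22.3 ± 4.41 to 6.41 ± 2.49 FPKM (-1.76 ± 0.08), SECTM1 by 1.26 ± 0.07, APOL1 by 1.15 ± 0.06 and IL1R1 by 1.06 ± 0.07. Of 21 JAK-STAT3 genes 16 fell and 0 rose (17 and 1 adjusted over the list alone, camera adjusted p = 1.16e-39) and of 22 interferon-stimulated genes 13 fell (16 adjusted over the list alone, camera adjusted p = 2.68e-31). Of 26 sterol genes 1 fell (0 adjusted over the list alone, camera adjusted p = 0.347) and of 20 FOXO targets 1 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.199). HAS2 (-0.07 ± 0.07, adjusted p = 0.888) and IGF1R (-0.04 ± 0.04, adjusted p = 0.924) did not pass.

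At 48 h C3 fell from 36.4 ± 13 to 4.19 ± 1.58 FPKM with LASN01 (-2.95 ± 0.09), PLA2G2A by 3.51 ± 0.25, CHI3L1 by 2.5 ± 0.14 and SOCS3 by 2.03 ± 0.06. HAS2 fell by 0.86 ± 0.13 to 3.71 ± 1.14 FPKM (adjusted p = 1.38e-06), CD44 by 0.51 ± 0.04 and THY1 by 0.55 ± 0.06, with 9 of 19 hyaluronan genes fallen and 2 risen (9 and 3 adjusted over the list alone, camera adjusted p = 0.00191). Acute phase genes fell, 9 of 10 with 1 risen over all genes and adjusted over the list alone (camera adjusted p = 9.42e-17). Contractile genes rose, 9 of 15 (10 adjusted over the list alone, camera adjusted p = 7.07e-06, adjusted p = 0.0904 with an estimated correlation), ACTA2 by 0.38 ± 0.11 (adjusted p = 0.00941), and so did COL1A1 (0.24 ± 0.04, adjusted p = 2.84e-05), the calcineurin regulator RCAN2 (1.14 ± 0.06) and RASSF2 (1.07 ± 0.08). Sterol genes had 1 risen and 2 fallen (0 and 2 adjusted over the list alone, camera adjusted p = 0.714). Of 8 measured adipogenesis genes 1 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.486), PPARG by 0.25 ± 0.06.

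Counts for LASN01 on top of both ligands were 207 risen and 361 fallen at 6 h and 1060 and 1207 at 48 h. Without the donor F library 372 and 577 were called at 6 h, and without donor F 897 genes. Without the donor block 0 rose and 86 fell at 6 h and 35 and 206 at 48 h; library numbers 1 to 48 and 49 to 96 alone gave 672 and 69 genes at 6 h and 1465 and 926 at 48 h.

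Teprotumumab moved the IGF-1 genes back in part. At 6 h YPEL3 rose from 1.77 ± 0.448 to 2.97 ± 0.913 FPKM (0.59 ± 0.07, adjusted p = 3.12e-06), below the 6 ± 0.803 FPKM of IL-11 alone, and KLHL24 (0.51 ± 0.08), PIK3IP1 (0.52 ± 0.09) and HBP1 (0.46 ± 0.06) rose. IGF1R rose by 0.36 ± 0.04 (adjusted p = 8.42e-07) and CTGF by 0.35 ± 0.05, while HAS2 fell from 26.3 ± 7.77 to 20.5 ± 6.97 FPKM (-0.37 ± 0.07, adjusted p = 0.00301), the methionine adenosyltransferase MAT2A by 0.27 ± 0.04 and the nucleolar NOP56 by 0.19 ± 0.03. Of 20 FOXO targets 5 rose (9 adjusted over the list alone, camera adjusted p = 4.81e-13). No sterol gene passed over all genes (1 fell adjusted over the list alone), though camera called the list (adjusted p = 2.31e-08, adjusted p = 0.0758 with an estimated correlation). SOCS3 did not pass (0.05 ± 0.08, adjusted p = 0.995), and of 21 JAK-STAT3 genes 1 rose (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.654).

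At 48 h SCD fell from 205 ± 66 to 148 ± 46.4 FPKM with teprotumumab (-0.47 ± 0.07, adjusted p = 1.83e-05), HMGCS1 by 0.35 ± 0.05 and STARD4, a sterol carrier, by 0.36 ± 0.06. In all 16 of 26 sterol genes fell (20 adjusted over the list alone, camera adjusted p = 6.57e-19). ZNF488 (0.72 ± 0.07), GALNT15 (0.52 ± 0.12) and ERBB3 (0.45 ± 0.06) had the opposite course. Of 13 mitochondrially encoded mRNAs 11 rose (12 adjusted over the list alone, camera adjusted p = 3.28e-17), MT-ND1 by 0.3 ± 0.05. SERPING1 rose by 0.37 ± 0.05 and PI16 by 0.36 ± 0.06. In the IGF axis 5 of 15 genes rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0153), with IGF1R at 0.14 ± 0.04 (adjusted p = 0.0198). HAS2 (-0.34 ± 0.13, adjusted p = 0.0924), SOCS3 (0.05 ± 0.06, adjusted p = 0.69) and COL1A1 (-0.01 ± 0.04, adjusted p = 0.967) did not pass. Of 12 genes of IL-6 family ligands and receptors 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.788), and the endothelial list had 0 of 3 called (camera adjusted p = 0.915).

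The teprotumumab counts were 65 risen and 10 fallen at 6 h and 493 and 380 at 48 h. They changed when single donors were left out. The IL-11 6 h library of donor F is in neither arm and acts on the 6 h counts only through the shared error. At 6 h 179 and 68 were called without the donor F library, 33 and 13 with scaling to summed fragments, 39 and 20 by limma-voom and 1 gene without the donor block; leaving out a donor gave 43 genes (A), 35 (B), 37 (C), 47 (D), 165 (F) or 33 (H). At 48 h leaving out a donor gave 460 (A), 424 (B) or 506 (C), and 0 genes were called without the donor block (528 at an unadjusted p under 0.05 in limma). Scaling to summed fragments gave 325 risen and 685 fallen at 48 h, quantile normalization 370 and 429, and limma-voom 478 and 1166. Library numbers 1 to 48 and 49 to 96 alone gave 76 and 0 genes at 6 h (307 at an unadjusted p under 0.05 in the latter) and 571 and 1 at 48 h. Both 528 and 307 are below the share of 0.05 of tested genes that chance gives on average.

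Set against each other in the presence of both ligands, LASN01 gave lower SOCS3 than teprotumumab at 6 h (-1.82 ± 0.08) and lower C3 (-3.19 ± 0.09) and PLA2G2A (-3.56 ± 0.25) at 48 h, while RASSF2 (1.35 ± 0.08) was higher. Counts were 311 risen and 549 fallen at 6 h (1404 genes in all without the donor F library, 1292 without donor F, 107 without the donor block) and 1547 and 1712 at 48 h (314 without the donor block). The runs of library numbers gave 968 and 90 genes at 6 h and 2597 and 1085 at 48 h. Compared with vehicle, the LASN01 arm had HAS2 at 0.81 ± 0.07 and YPEL3 at -1.71 ± 0.07 at 6 h and SCD at 0.98 ± 0.07 and CTGF at -1.01 ± 0.07 at 48 h. The teprotumumab arm had SOCS3 at 1.69 ± 0.08 and YPEL3 at -1.08 ± 0.07 at 6 h and C3 at 2.64 ± 0.09 at 48 h. Of 10 acute phase genes 7 fell in the LASN01 arm against vehicle at 48 h (camera adjusted p = 9.49e-06).

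Against vehicle these antibody arms had 1382 risen and 1507 fallen genes with LASN01 at 6 h and 1886 and 2068 at 48 h, and 1146 and 1243 with teprotumumab at 6 h and 2127 and 2084 at 48 h. Without the donor F library 4299 and 3722 genes were called at 6 h, without the donor block 681 and 388 at 6 h and 307 and 610 at 48 h. Library numbers 1 to 48 and 49 to 96 alone gave 3408 and 407 genes for LASN01 at 6 h, 2629 and 2035 at 48 h, and for teprotumumab 3087 and 313, and 2661 and 2314. Scaling to summed fragments gave 1916 risen and 910 fallen for LASN01 at 6 h and, for teprotumumab, 1517 and 769 at 6 h and 1666 and 2766 at 48 h. Teprotumumab with both ligands still differed from IL-11 alone, HAS2 by 0.59 ± 0.07 and YPEL3 by -0.94 ± 0.07 at 6 h and FABP3, a fatty acid carrier, by 0.68 ± 0.06 and GALNT15 by -0.66 ± 0.12 at 48 h. Here 614 genes were higher and 657 lower at 6 h (1529 in all without the donor F library, 789 without donor D, 86 without the donor block; 1185 and 311 with scaling to summed fragments), and 629 and 561 at 48 h (1 without the donor block; 488 and 766 with scaling to summed fragments). The runs of library numbers gave 1144 and 28 at 6 h and 582 and 163 at 48 h.

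To put the antibodies on common scales, each donor was scored on genes called in the other 7 donors. With IL-11 the IL-11 response score rose by 0.48 ± 0.09 at 6 h and 0.55 ± 0.06 at 48 h (mean ± SD, n = 8, exact p = 0.00781, the smallest possible), and LASN01 left 8.99 ± 9.38% of it at 6 h (95% interval 1.15 to 16.8) and 3.35 ± 2.3% at 48 h (1.43 to 5.28). With both ligands LASN01 left 15.9 ± 11.2% and 17.4 ± 5.36%, and teprotumumab 95.5 ± 20.1% and 99.4 ± 8.42%, a difference of -0.02 ± 0.07 (exact p = 0.688, n = 8) and -0.01 ± 0.04 (exact p = 0.664, n = 8) from IL-11 + IGF-1. Under LASN01 this score was higher with IGF-1 than without it in each donor at 48 h. No arm held IGF-1 without IL-11, so a direct effect of IGF-1 on these genes cannot be told from IL-11 response left. The IGF-1 response score rose by 0.43 ± 0.08 at 6 h and 0.41 ± 0.05 at 48 h, and teprotumumab left 59.5 ± 10.6% (50.6 to 68.4) and 54.9 ± 9.6% (46.9 to 62.9). LASN01 moved it by 0.01 ± 0.02 (exact p = 0.375, n = 8) and 0 ± 0.04 (exact p = 0.836, n = 8). In the runs of library numbers 1 to 48 and 49 to 96 (n = 4 each) the IL-11 score rose by 0.55 and 0.41 at 6 h and 0.59 and 0.51 at 48 h, the IGF-1 score by 0.47 and 0.38 and by 0.46 and 0.36, and teprotumumab left 64.6% and 54.5% at 6 h and 52.4% and 57.5% at 48 h. Without the donor F library LASN01 left 6.98% and teprotumumab 63.5% at 6 h.

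**Figure D3:**
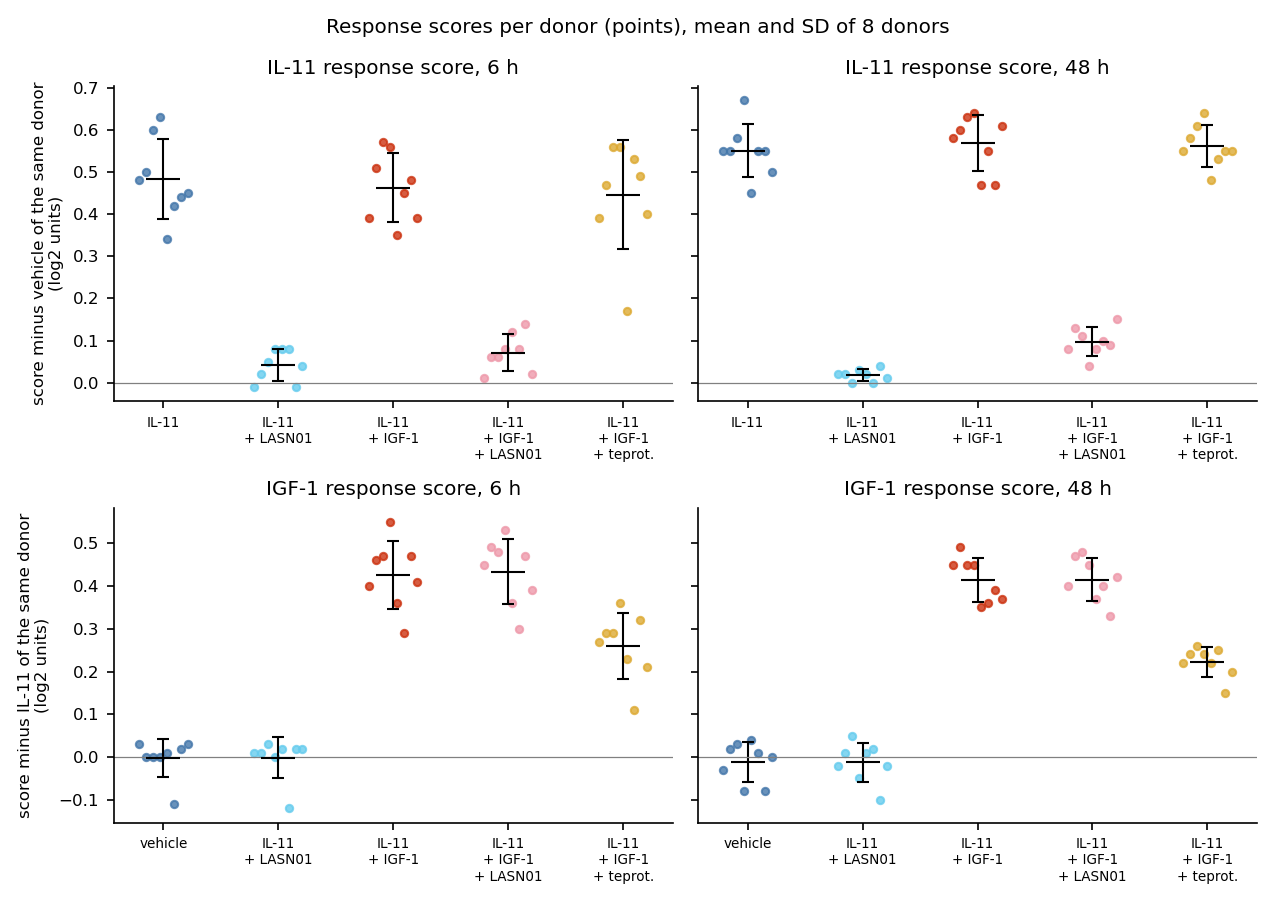
IL-11 response score minus vehicle and IGF-1 response score minus the IL-11 arm of the same donor (log2 units), 1 point per donor with mean and SD (n = 8), at 6 h and 48 h. The IL-11 score is lower in both arms with LASN01 than in those without, and the IGF-1 score in the teprotumumab arm lies between IL-11 and IL-11 + IGF-1.

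Comparisons that share no library were set beside each other. They still share each gene's error from the fit of a time. The overlaps given as by chance take the calls as independent and can therefore be too low. Of 982 genes changed by LASN01 with IL-11 alone at 6 h and 568 with IGF-1 present, 440 were in both (43.9 by chance), and all 440 moved the same way; at 48 h 1628 of 2651 and 2267 were in both (473 by chance), 1626 the same way. Across all genes these changes correlated with r = 0.48 at 6 h and 0.74 at 48 h; genes are not independent replicates. Among 75 genes changed by teprotumumab at 6 h, 73 were also changed by IGF-1 in cells with LASN01 (15.3 by chance), all in the opposite direction, and at 48 h 629 of 873 (271 by chance), 628 in the opposite direction. IGF-1 in cells with LASN01 changed 1235 genes upward and 1362 downward at 6 h, and 1891 and 2055 at 48 h.

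The effect of IL-11 differed between times for many genes. The difference (48 h minus 6 h) was 3.99 ± 0.27 for PLA2G2A, 2.96 ± 0.11 for C3, 2.5 ± 0.15 for CHI3L1 and 1.03 ± 0.15 for HAS2 (adjusted p = 1.2e-07), and -0.92 ± 0.08 for APOL2 and -0.29 ± 0.05 for IGF1R; SOCS3 did not pass (0.14 ± 0.1, adjusted p = 0.424). In all, 607 genes had a higher and 415 a lower change at 48 h (22 in all without the block), 1546 and 1441 for both ligands (317 without the block), 338 and 432 for LASN01 with IL-11 (14), 187 and 323 for LASN01 with both ligands (12), and 11 and 36 for teprotumumab (0 without the block, 138 without the donor F library). The effect of LASN01 differed with and without IGF-1 for 1 gene at 6 h, the transmembrane protein gene SUSD6 (0.31 ± 0.06, adjusted p = 0.0311; 0 genes without the donor F library and 0 without the block), and for 0 at 48 h (884 at an unadjusted p under 0.05 in limma). In vehicle, 3903 genes were higher at 48 h than at 6 h and 3788 lower. The small proteoglycan ASPN rose by 3.52 ± 0.13 and HAS2 fell by 2.4 ± 0.18. Of 26 cell cycle genes 26 fell (camera adjusted p = 9.45e-22), while 19 of 20 ATF4 and amino acid genes rose (camera adjusted p = 2.54e-12, adjusted p = 0.0518 with an estimated correlation). This fit of vehicle blocked on the donor only and took its error from all 96 libraries. Deviations of a donor's libraries correlated more within a time (median r 0.64) than across times (0.41). These calls, standard errors and p values can therefore overstate the evidence for an effect of time.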

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

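All tests of explanations below were chosen after the results were seen, while the number of label swaps, 40 with the real one included, was set before the data were examined.

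Genes of the myofibroblast contractile list fell with IL-11 at 48 h, 10 of 15 measured, among them ITGA11 (-0.49 ± 0.03) and TPM1 (-0.51 ± 0.06). The tables argue against scaling, since 10 of the 10 were still called after quantile normalization or scaling to summed fragments, and against the runs of library numbers, since all 15 genes were below 0 in both runs, with medians of -0.34 in numbers 1 to 48 and -0.15 in 49 to 96. The 6 measured markers of pericytes and smooth muscle cells showed no shared fall, from -0.1 ± 0.05 (NOTCH3) to 0.87 ± 0.07 (ABCC9), 3 risen and 0 fallen. They cannot decide on a lower share of these cells, since ABCC9 and KCNJ8 rose with IL-11 and fell with LASN01. Smooth muscle actin, ACTA2, is itself in the contractile list. Even NOTCH3, the lowest, lay 0.19 ± 0.11 (SD, n = 8) above the mean of all 15 contractile genes, -0.28. Of 3 measured skeletal muscle markers 2 fell, with a mean of -0.25. A lower share of muscle fibres is argued against, since all 14 fixed markers together lost 5.67 ± 2.58 FPKM while the contractile genes lost 100 ± 51.4 FPKM (SD, n = 8). Muscle precursors were not tested, so a lower share of them stays open, as does that of pericytes or smooth muscle cells. A change of the fibroblasts themselves stays open too, and so does whether protein follows.

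Part of the IGF-1 response was left with teprotumumab, 59.5 ± 10.6% at 6 h and 54.9 ± 9.6% at 48 h (n = 8). A few donors are no account of it, since the lowest share in any donor was 36.4%. The lowest mean share was 54.9% under quantile normalization or scaling to summed fragments. A factor per library nearly cancels in a score of risen minus fallen genes. Scaling to summed fragments could therefore hardly have changed the share, and this check does not decide on scaling. IGF-1 could act through the insulin receptor, or 10 µg/mL may not block all receptors; a single dose leaves both open.

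Interferon-stimulated genes rose with IL-11 at 6 h, 14 of 22 measured, among them GBP2 (1.2 ± 0.08) and IFIT3 (0.82 ± 0.05). Interferon in the IL-11 preparation is argued against by LASN01, which left -7.79 ± 16.3% of the rise (SD, n = 8). The donor F library is argued against by 12 of the 14 genes still called without it; BST2 went from 0.48 ± 0.16 to 0.29 ± 0.13 and OAS3 stayed at 0.14 ± 0.05. Scaling is argued against by a median of 0.48 under the alternative nearer 0, against 0.5 as planned. Still called were 11 of the 14 when scaled to summed fragments, where BST2 stood at 0.46 ± 0.16, OAS1 at 0.27 ± 0.09 (0.28 ± 0.08 as planned) and OAS3 at 0.12 ± 0.05, calls near the threshold that ended with little change in fold. As a hypothesis, these genes may follow directly from signalling of the IL-11 receptor; secondary interferon made by the cells was not tested.

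Which results could come from a chance division of donors was asked by swapping the labels of both arms within donors, 40 divisions with the real one included. The smallest share that 40 divisions can give is 1 of 40, and it was not corrected over the results asked. Chance can be excluded at that level for a result where no other division called as many genes. This held for IL-11 versus vehicle (1364 genes against at most 509 at 6 h, 2734 against 1468 at 48 h), IL-11 + IGF-1 versus vehicle (3853 and 1829, 5080 and 3136), IL-11 + IGF-1 versus IL-11 (3175 and 1505, 3149 and 1280) and LASN01 on IL-11 (982 and 295, 2651 and 1394). It held for LASN01 with both ligands (568 and 137, 2267 and 1157), teprotumumab with both ligands (75 and 0, 873 and 4), LASN01 against teprotumumab (860 and 220, 3259 and 1423), and with both ligands against vehicle for LASN01 (2889 and 1118, 3954 and 2178) and teprotumumab (2389 and 851, 4211 and 2372). It held for teprotumumab with both ligands against IL-11 (1271 and 297, 1190 and 167) and for vehicle at 48 h against 6 h (7691 and 6156). Differences between times had 1022 against 190 for IL-11, 2987 and 1142 for both ligands, 770 and 138 for LASN01 on IL-11, 510 and 84 for LASN01 with both ligands, and 47 and 0 for teprotumumab. The difference of the LASN01 effect with and without IGF-1 had 1 against 0 at 6 h, a single gene that was not called without the donor F library or without the donor block, so chance stays open there. Chance was not excluded for IL-11 + LASN01 versus vehicle, 0 genes with 40 of 40 divisions as high at both times. Neither was it for the LASN01 difference at 48 h, 0 genes with 1 in the highest other division and 40 of 40 as high. A real count of 0 is matched by any division, so the swaps could not decide there.

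Some values stood far from the other 7 donors of their group by Dixon's ratio, which chance gives in about 1 in 20 groups. Among 48 groups of library measures 11 did so. Fragments were 24.45 M in vehicle at 6 h (donor F), 30.8 M in IL-11 at 6 h (A) and 34.54 M in IL-11 + IGF-1 at 48 h (A). Genes above 0 numbered 21884 in vehicle (F) and 15977 in IL-11 (F) at 6 h. Mitochondrial fragments were 0.09193% in IL-11 at 6 h, 1.84% in IL-11 + IGF-1 + LASN01 at 6 h, 2.295% in IL-11 + LASN01 at 48 h and 2.327% in IL-11 + IGF-1 + LASN01 at 48 h, all donor F. The 10 highest genes held 28.63% in IL-11 (F) and 16.85% in the teprotumumab arm (E) at 6 h. Of 18 score groups 2 did so: the IL-11 score of the teprotumumab arm at 6 h, 0.17 (E), and the IGF-1 score of IL-11 + LASN01 at 6 h, -0.12 (F).

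Of 187 groups of genes named in the report 22 did so, 11 of them donor F at 6 h, and about 9 would by chance. With IL-11 at 6 h donor F had OSMR at 0.17, IL6ST at -0.4, CCL2 at 0.1, PTX3 at 2.04, TGFB1 at -0.61 and FAM180A at -3.7, donor G had MCM4 at -0.52 and donor C KRT18 at 0.11. At 48 h COL3A1 was -0.09 (E) and CXCL12 0.93 (D). LASN01 on IL-11 had NNMT at -2.25, CCL2 at 0.51 and TGFB2 at 1.8 in donor F and SOCS3 at -1.56 in donor G at 6 h, and COL3A1 at 0.1 (E) and CDC20 at 0.85 (D) at 48 h. IL-11 + IGF-1 against IL-11 had SCD at 1.24 (F), HSPA8 at 1.06 (F) and CTGF at -0.17 (G) at 6 h and SERPING1 at -1.09 (G) at 48 h. RASSF2 was 1.4 in donor A for LASN01 with both ligands at 48 h, and TNFAIP6 2.74 in donor G for both ligands against vehicle at 48 h. The low-complexity donor F library enters the 6 h comparisons among these and none of those at 48 h, and no biological explanation was tested.

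Effects differed between 6 h and 48 h, given as the change at 48 h minus that at 6 h. For IL-11, with 1022 genes, PLA2G2A stood at 3.99, C3 at 2.96, CHI3L1 at 2.5, NFE2 at 2.08, RCAN2 at -0.97, APOL2 at -0.92, NOV at -0.91 and CHODL at -0.87. For both ligands, with 2987 genes, PLA2G2A stood at 3.44, NFE2 at 2.5, CLCA2 at 2.32, C3 at 2.24, ANKRD1 at -1.33, OMD at -1.12, SERPINB2 at -1.09 and RCAN2 at -1.07. For LASN01 on IL-11, with 770 genes, COL5A3 stood at 1.01, NOV at 0.91, RCAN2 at 0.89, APOL2 at 0.88, PLA2G2A at -3.85, C3 at -2.74, CHI3L1 at -2.33 and NFE2 at -1.8. For LASN01 with both ligands, with 510 genes, RCAN2 stood at 1.22, TAP2 at 0.84, COL15A1 at 0.83, PLA2G2A at -3.28, C3 at -2.67, CHI3L1 at -2.27 and NFE2 at -1.8. For teprotumumab, with 47 genes, ZNF488 stood at 0.64, ADAMTSL5 at 0.42, PI16 at 0.33, TP53I11 at 0.32, MMP1 at -0.69, METTL7A at -0.47, KLHL24 at -0.45 and PTN at -0.45. The LASN01 effect with and without IGF-1 differed for 1 gene at 6 h, SUSD6 at 0.31.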

How the results depend on the processing

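These results come from 8 donors of a single disease with no healthy donors, from a single preparation per donor, arm and time, from RNA only, and from 1 dose per antibody. Counts are genes called. LASN01 and teprotumumab stand here for these antibodies added to both ligands unless stated. Without the donor block, counts were 133 (6 h) and 304 (48 h) for IL-11 versus vehicle, 1105 and 1179 for both ligands versus vehicle, 734 and 180 for both ligands versus IL-11, 117 and 277 for LASN01 on IL-11 alone, 86 and 241 for LASN01, 1 and 0 for teprotumumab, 107 and 314 between the antibodies, 681 and 307 for LASN01 versus vehicle, 388 and 610 for teprotumumab versus vehicle, and 86 and 1 for teprotumumab versus IL-11. Differences between times fell to 22 (IL-11), 317 (both ligands), 14 (LASN01 on IL-11 alone), 12 (LASN01) and 0 (teprotumumab), and the LASN01 difference at 6 h to 0. With a mean FPKM of at least 5, fewer genes were tested, with 845 and 1742 for IL-11 versus vehicle, 2323 and 3159 for both ligands versus vehicle, 1931 for both ligands versus IL-11 at 6 h, 614 and 1746 for LASN01 on IL-11 alone, 369 and 1507 for LASN01, 530 between the antibodies at 6 h, 1739 for LASN01 versus vehicle at 6 h, and 1528 and 2688 for teprotumumab versus vehicle. Library numbers 1 to 48 alone gave, at 48 h, 1733 for IL-11 versus vehicle, 1635 for LASN01 on IL-11 alone, 1465 for LASN01, 571 for teprotumumab, 2629 and 2661 for LASN01 and teprotumumab versus vehicle, and 582 for teprotumumab versus IL-11. Numbers 49 to 96 gave 169 and 1323 for IL-11 versus vehicle, 850 and 2805 for both ligands versus vehicle, 674 and 1133 for both ligands versus IL-11, 135 and 1339 for LASN01 on IL-11 alone, 69 and 926 for LASN01, 0 and 1 for teprotumumab, 90 and 1085 between the antibodies, 407 and 2035 for LASN01 versus vehicle, 313 and 2314 for teprotumumab versus vehicle, 28 and 163 for teprotumumab versus IL-11, and 3 for IL-11 + LASN01 versus vehicle at 48 h. With only both compared arms in the fit the counts were 322 (IL-11 versus vehicle, 6 h), 1312 (both ligands versus IL-11, 6 h), 330 (LASN01 on IL-11 alone, 6 h), 1376 (LASN01, 6 h), 417 (teprotumumab, 48 h), 1575 (teprotumumab versus vehicle, 6 h) and 92 (teprotumumab versus IL-11, 6 h). With no filter teprotumumab had 49 and 514 and, versus IL-11, 814 at 6 h; limma-voom gave 1644 for teprotumumab at 48 h and 2 for IL-11 + LASN01 versus vehicle at 48 h, and scaling to summed fragments 46 for teprotumumab at 6 h. Without the IL-11 6 h library of donor F, a setting chosen after seeing the data, LASN01 had 949, teprotumumab 247, the antibodies between them 1404, teprotumumab versus vehicle 3722, the time difference of teprotumumab 138 and the LASN01 difference at 6 h 0. Without 3 libraries, also chosen after seeing the data, the 6 h counts were 1105 for LASN01, 208 for teprotumumab, 1355 between the antibodies, 4804 for LASN01 versus vehicle and 3985 for teprotumumab versus vehicle. Leaving out 1 donor gave 33 to 165 for teprotumumab at 6 h and 424 to 966 at 48 h, 391 to 897 for LASN01 at 6 h, 608 to 1292 between the antibodies at 6 h, 789 to 1629 for teprotumumab versus IL-11 at 6 h, and 0 to 1 for IL-11 + LASN01 versus vehicle at 48 h. Pseudocounts, quantile normalization and plain empirical Bayes left genes called per comparison within 1.5-fold of those planned, as the top 50 genes did for the shares of scores removed. Differences between effects were not run with these. Quantile normalization gave 370 risen and 429 fallen for teprotumumab at 48 h, against 493 and 380; median-ratio scaling was void because the FPKM already carry it. Named genes keeping their call were fewer by more than 1.5-fold in 17 of 20 comparisons without the donor block, 9 with numbers 49 to 96, 7 with a mean FPKM of at least 5, 3 with only both arms and 2 with numbers 1 to 48; lists called were so in 12 of 22 without the block. The estimated camera correlation left fewer lists in each of 22 comparisons, by more than 1.5-fold in 20. No named gene was called in the opposite direction in any setting run. Without the donor block the pairing is ignored, although each donor is in every arm, and the spread between donors enters the error. Libraries of a donor at the same time correlated with a median r of 0.64, against -0.1 between donors. Numbers 49 to 96 hold 4 donors, with the IL-11 6 h library of donor F among their libraries. That library also enters the error of 6 h comparisons that do not hold its arm. The causes of the other differences were not tested. Realignment, other aligners and models of isoforms were not run. At a median of 17.4 M fragments, genes under an FPKM of 1 are mostly out of reach, and of genes simulated with a 1.1-fold change 4 of 47 were called. That simulation changed 200 genes, fewer than most real comparisons called, and can understate their reach.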

Other observations

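The tests of both hypotheses here were chosen after the results were seen. At 48 h IL-11 raised C3 to 59.9 ± 19.5 FPKM and PLA2G2A, a secreted phospholipase, by 4.06 ± 0.25, while at 6 h C3 stood at 4.27 ± 1.65 FPKM with IL-11. SOCS3 had already risen at 6 h (1.97 ± 0.08), and no cause of the later rise of C3 and PLA2G2A was tested. At 48 h IGF-1 lowered C3 (-0.73 ± 0.09) and SERPING1 (-0.7 ± 0.05) and raised HAS2 (0.53 ± 0.13) on top of IL-11, so at 48 h the ligands moved these complement genes in opposite directions and HAS2 in the same direction. At 6 h HAS2 did not pass with IL-11 (-0.08 ± 0.07, adjusted p = 0.487), while IGF-1 raised it by 0.96 ± 0.07.

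A hypothesis is that the IGF-1 response does not depend on IL-11 signalling. In cells with LASN01 the IGF-1 score change at 48 h was 104 ± 9.57% of that without LASN01 (n = 8, 95% interval 96.3 to 112), which leaves room for IGF-1 acting alone; an arm with IGF-1 and no IL-11 would test it. Another hypothesis is that teprotumumab leaves a different share of the FOXO response and of the sterol response. At 6 h 67.1 ± 13.2% of the FOXO change and 59.6 ± 9.24% of the sterol change were left (exact two-sided p = 0.0938, n = 8). At 48 h 62.3 ± 36.8% of the FOXO change and 53.2 ± 17.8% of the sterol change were left (exact two-sided p = 0.391, n = 8), so it stays open, and a series of teprotumumab doses would test it.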
